A study of Mus musculus with 2 samples.

How the data were processed

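Total RNA depleted of ribosomal RNA was sequenced from mouse erythroblasts, the nucleated precursors of red blood cells. Per the labels, the cells were primary cells of male C57BL/6J mice aged 5 to 6 weeks, and each library was made from 100 ng of RNA with a ScriptSeq kit. The labels give 1 group with 2 biological replicates, each a biosample of its own under 1 shared donor record, so the spread between them may be partly technical. They also give a size range of 200 to 764 for replicate 1 and of 138 to 1000 for replicate 2, without a unit.

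Each library had a table per gene and a table per transcript. Per the labels the assembly was mm10, and the deposited text records name GENCODE annotation release M4. The aligner, the quantification program and their versions are not given in the sources used here. Per the file headers, the authors' tables hold expected counts, which are estimated counts that need not be whole numbers, with a posterior mean of each count and its standard deviation. Per the file headers, the tables also hold deposited TPM, a share over all listed features, posterior mean TPM with bounds of a credibility interval, and deposited FPKM. Per the file headers, the transcript tables give the percent of a gene's TPM held by each transcript. Each file holds 1 library, and no values were pooled.

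The gene tables had 69691 features: 43346 Ensembl genes, 26248 tRNA features and 97 spike-in features. Of the Ensembl genes, 42462 (98.0%) matched GENCODE release M21 by identifier without version. Release M21 is on the same assembly (GRCm38) and gave symbols, RNA classes, coordinates and GC content. Features without an Ensembl gene held 8 and 28 counts in replicates 1 and 2 and were left out of library sizes and ratios. The members Ahsp and Snhg1 of the gene lists below were not analysed here, nor were the other sequencing tracks of the series.

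Levels were described with deposited TPM. Because TPM is a share of all features, levels were also expressed as coding-scaled TPM, rescaled so that 21461 nuclear protein-coding genes of a library sum to 1000000. The median difference between length and effective length of features longer than 2 kb was 190 bases in replicate 1 and 152 bases in replicate 2. A gene counted as detected with a TPM of at least 1 in both libraries. Globin shares, RNA class shares and transcript shares were computed per library and are given as mean ± SD with n = 2. Gene list levels are medians over members, with the median percentile rank among the 12895 protein-coding genes that had a TPM above 0 in either library.

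The libraries were compared gene by gene. Expected counts were rounded to whole numbers and scaled with TMM factors from edgeR 4.0.16 in R 4.3.3. The log2 ratio of replicate 2 over replicate 1 was computed for genes with a mean count of at least 100. Each ratio has an exact Clopper-Pearson 95% interval, which covers counting error only, since no molecular identifiers were used. No gene was tested and no p-value is given, since each side of this comparison is a single library. A median log2 ratio of a gene list was placed among those of 10000 random lists of the same size, matched on mean count in 20 classes, for members with a mean count of at least 10. This ranking describes 1 pair of libraries and treats the members of a list as independent, which genes regulated together are not. The biological coefficient of variation came from edgeR with an intercept-only design over 12757 genes. DESeq2 1.42.0 size factors were an alternative. Genes whose posterior standard deviation exceeded 3 times the square root of the count were marked as sharing reads with similar sequences. Where a library had 0 counts, a fold was computed against 3 counts. Counting and plotting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

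The groupings, the gene lists, the comparisons and most alternatives were chosen before the data were examined. There were 23 gene lists: adult globins, embryonic globins, heme synthesis, iron uptake and handling, red cell membrane and skeleton, red cell enzymes, erythroid transcription factors, erythropoietin signalling, late maturation, cell cycle, stem and progenitor cells, megakaryocytes, neutrophils, monocytes and macrophages, B cells, T and NK cells, mast cells with basophils and eosinophils, endothelium and stroma, other organs, interferon response, immediate early and heat shock genes, long noncoding RNAs, and Y-linked genes. The genes named are members of these lists, the 15 nuclear protein-coding genes and the 5 genes of other classes with the highest mean TPM, the 10 largest log2 ratios in each direction, and the leading transcripts of 10 genes with known red cell promoters or splicing. The 10 largest ratios were taken among genes whose interval excludes 0. Chosen after the values were seen were the rescaling with globins kept, the detection limit in coding-scaled TPM and small RNA relative to coding TPM. So were the restriction of detected genes and of ratios to protein-coding genes, and the variance by count class. The tests of fragment length, nuclear RNA and lymphoid genes, the interval of the maturation difference and any gene described as such were also chosen afterwards.

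The computations were tested on simulated data. In libraries drawn with Poisson noise from the real means of 8203 genes, 100% of 200 genes changed by 1.5 on the log2 scale were at least 2-fold apart, against 0% of unchanged genes, and 95.6% of the intervals held the true ratio. Simulated coefficients of variation of 0.1 and 0.3 over 12757 genes were recovered as 0.100 and 0.299. These tests check the computations only. The real libraries differed more, with a coefficient of variation of 0.560, and recovery and coverage at that spread were not tested.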

Results

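Total RNA from mouse erythroblasts was measured in 2 libraries of 1 group, described here as replicates 1 and 2. Replicate 1 held 37312632 expected counts and replicate 2 held 22464752. A count of 0 therefore allows up to 0.0804 and 0.134 CPM. The 10 genes with most counts held 38.2% and 33.6% of each library. Counts of 12750 genes differed by a chi-square of 312 per degree of freedom, so the libraries were not copies of each other. With 1 group there is no contrast of conditions. The questions are which genes these cells express, at what level, and how closely the replicates match. Values are mean ± SD with n = 2 unless given per replicate, and coordinates are on GRCm38.

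Adult globin genes were the most abundant nuclear protein-coding genes by mean TPM. In replicate 2 alone, Gm10800 (TPM of 1440) stood above the globin gene Hba-a1 (1076). Hba-a2 and Hba-a1 encode alpha globin, and Hbb-bs and Hbb-bt encode beta globin. Together they held 35.8% ± 4.21 of nuclear protein-coding TPM and 10.1% ± 0.864 of nuclear protein-coding counts. Of deposited TPM, which is dominated by small RNAs, they held 3.31% ± 1.49, and of all counts 5.59% ± 0.859. Hba-a2 (chromosome 11, 32296489 to 32297298) had a TPM of 24060 ± 11029, and Hba-a1 (chromosome 11, 32283511 to 32284465) one of 2004 ± 1312. Hbb-bt (chromosome 7, 103812524 to 103813996) had a TPM of 3901 ± 795, and Hbb-bs (chromosome 7, 103826534 to 103828096) one of 3181 ± 1723. The alpha genes are near-identical, so their separate levels rest on an estimated split of reads. The posterior standard deviation in replicate 1 was 168 counts for each alpha gene and 542 for each beta gene. This is under the limit used here for marking shared reads. The ratio of alpha to beta globin was 3.60 ± 0.463 by TPM and 2.65 ± 0.395 by counts. The embryonic globins were at or near 0: Hbb-y and Hbb-bh1 had 0 counts in both libraries, and Hba-x had 7 and 12 counts.

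Of 8 erythroid lists, 7 stood near the top of the protein-coding genes, with median percentiles of 92.2 for transcription factors to 99.99 for adult globins. Erythropoietin signalling, at percentile 55.5, did not. Of the 86 genes in these lists, 77 were detected, with a median TPM of 38.0 ± 8.11 and a median percentile of 97.6 among 12895 genes. With TPM rescaled so that the nuclear protein-coding genes of a library sum to 1000000, their median was 428 ± 56.1. This unit, called coding-scaled TPM from here on, was chosen for gene levels after the small RNA shares were seen. Detected means a deposited TPM of at least 1 in both libraries, and the number of list members at 1 or more coding-scaled TPM in both is given where it differs.

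All 8 heme synthesis genes were detected, with a list median of 821 ± 72.4 coding-scaled TPM. Alas2, the first enzyme of heme synthesis in red cell precursors, stood at 3833 ± 345, Urod at 1304 ± 366 and Fech, which inserts iron, at 974 ± 48.6. Of 12 iron genes 10 were detected, with a median of 193 ± 0.0913. Tfrc, the transferrin receptor, stood at 3198 ± 474 and Slc25a37, the mitochondrial iron importer, at 2439 ± 175. Steap3 and Flvcr1 stayed under the detection limit, and all 12 reached 1 coding-scaled TPM.

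All 18 genes of the red cell membrane and skeleton were detected, with a median of 916 ± 75.8 coding-scaled TPM. Slc4a1, the anion exchanger known as band 3 (chromosome 11, 102348824 to 102366203), stood at 7384 ± 810. Epb41 stood at 3273 ± 78.5 and Sptb, which encodes a beta spectrin, at 961 ± 167. Icam4 was the lowest member, at 28.4 ± 11.1. Of 10 red cell enzyme genes 9 were detected, with a median of 369 ± 95.7. Among them Gpx1, a glutathione peroxidase, stood at 5104 ± 489, Car2, a carbonic anhydrase, at 2917 ± 368, and Bpgm, which makes 2,3-bisphosphoglycerate, at 1951 ± 339. Pklr was under the limit in deposited TPM, at 5.95 ± 0.00487 coding-scaled TPM, and all 10 reached 1 in that unit.

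Of 13 erythroid transcription factors 12 were detected, with a median of 93.5 ± 6.50 coding-scaled TPM. Sox6 (798 ± 127), Nfe2 (683 ± 32.3) and Lmo2 (622 ± 39.1) stood above Klf1 (106 ± 24.2), Tal1 (103 ± 6.53) and Gata1 (41.7 ± 15.5). Bcl11a was under the limit in deposited TPM, and all 13 reached 1 coding-scaled TPM. The erythropoietin signalling list was split. Bcl2l1, an inhibitor of apoptosis, stood at 917 ± 96.3, Pim1 at 441 ± 64.4, the receptor gene Epor at 76.1 ± 17.4 and Jak2 at 54.0 ± 6.73. The other 5 of its 9 members were under the limit in deposited TPM, among them Cish (3.49 ± 2.04 coding-scaled TPM) and Socs3 (1.46 ± 0.186), while 8 of 9 reached 1 coding-scaled TPM. The list median was 8.95 ± 2.81.

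Genes of late maturation and genes of the cell cycle were detected side by side. All 12 late maturation genes were detected, with a median of 433 ± 52.9 coding-scaled TPM. Tfdp2 stood at 2002 ± 96.5, Bnip3l, a receptor for the clearance of mitochondria, at 1231 ± 115, and Xpo7, a nuclear export receptor, at 1176 ± 115. All 22 cell cycle genes were detected, with a median of 94.4 ± 3.76. Mki67 stood at 1390 ± 29.5, Top2a at 385 ± 45.0, Pcna at 255 ± 18.8 and Cdk1 at 88.8 ± 9.65. Replication-dependent histone genes held 4.28% and 4.30% of coding TPM in replicates 1 and 2, and 59 of 64 were detected. Of 12 stem and progenitor genes only Myb (61.3 ± 9.96) and Kit (16.1 ± 5.54) were detected by deposited TPM, while 8 reached 1 coding-scaled TPM, and the list median was 3.23 ± 0.151.

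Genes of neutrophil granules were as abundant as several erythroid lists. All 14 neutrophil genes were detected, with a median of 398 ± 97.2 coding-scaled TPM and a median percentile of 97.7. S100a8 (chromosome 3, 90668978 to 90670035) stood at 8070 ± 918 and S100a9 at 6041 ± 1769, both among the 15 highest nuclear protein-coding genes. Ngp stood at 2339 ± 865, Camp at 1180 ± 140, Mpo, the myeloperoxidase gene, at 854 ± 302, and Elane, which encodes neutrophil elastase, at 376 ± 125.

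Other myeloid genes were lower and lymphoid genes were near 0. Of 13 monocyte and macrophage genes 11 were detected (13 by coding-scaled TPM), with a median of 31.1 ± 4.46 coding-scaled TPM. Lyz2, which neutrophils also express, stood at 2068 ± 272, and C1qa at 37.1 ± 0.447. Of 7 mast cell, basophil and eosinophil genes 6 were detected (7 by coding-scaled TPM), with a median of 44.4 ± 16.7, and Prg2 was highest at 490 ± 56.5. Of 12 megakaryocyte genes 3 were detected, namely Itga2b (91.4 ± 19.5), Fli1 (25.3 ± 3.34) and Vwf (25.2 ± 4.52), while 6 reached 1 coding-scaled TPM, and the median was 2.60 ± 0.221. Jchain (39.1 ± 1.12) was the only detected member of 12 B cell genes, of which 2 reached 1 coding-scaled TPM, with a median of 0.303 ± 0.326. Nkg7 (20.3 ± 5.89) was the only detected member of 10 T and NK cell genes, of which 3 reached 1 coding-scaled TPM, with a median of 1.05 ± 0.358. None of 9 endothelium and stroma genes was detected (3 by coding-scaled TPM), with a median of 0.267 ± 0.377. Among 12 genes of other organs, Gfap stood at 49.3 ± 5.54 and the other 11 had 0 counts in both libraries.

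**Figure D1:**
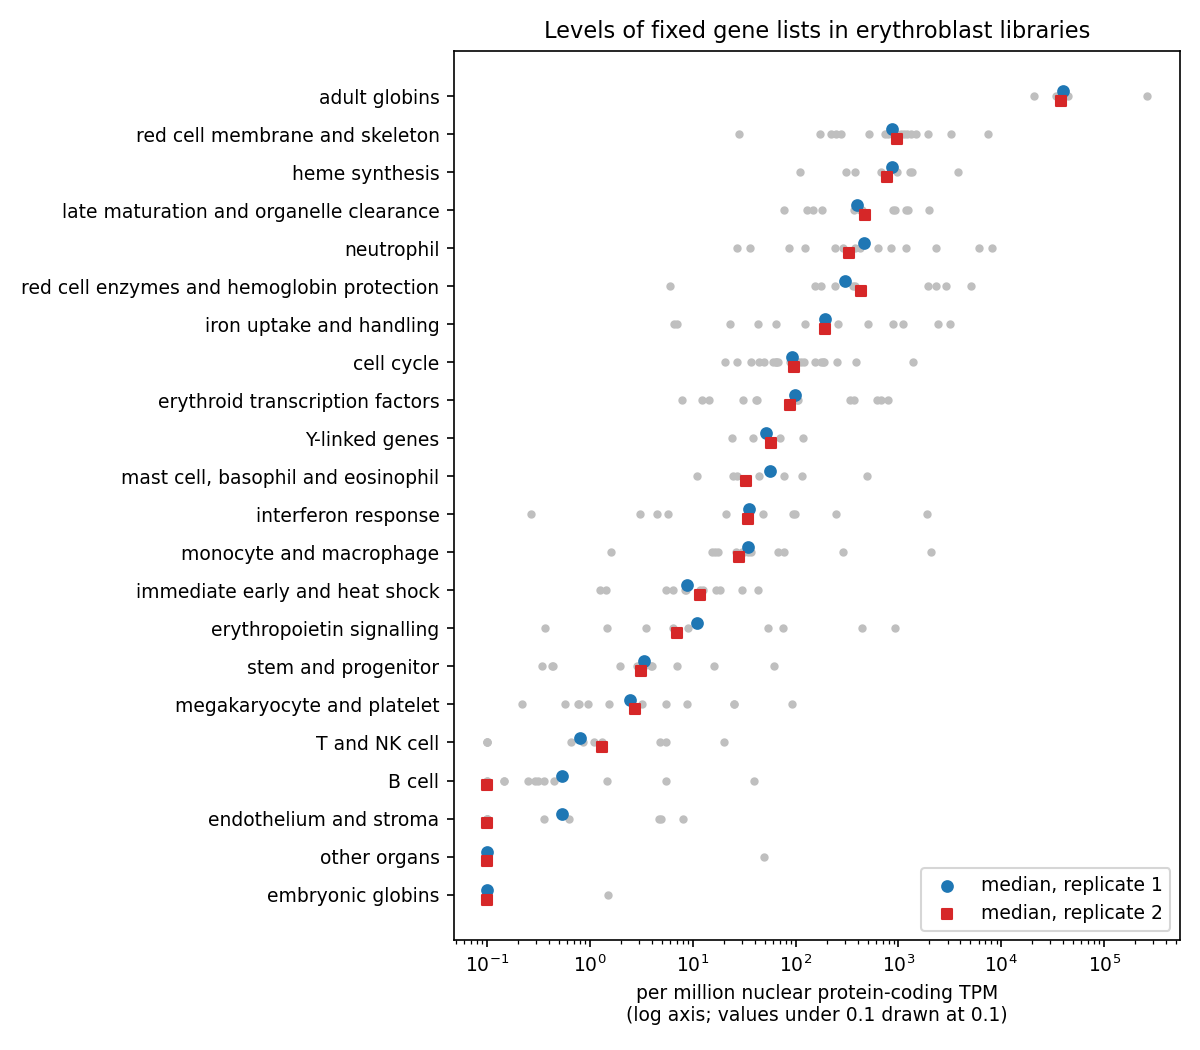
Levels of 22 gene lists on a log axis in coding-scaled TPM, where grey points are members (mean of both libraries) and the blue circle and red square are the list medians in replicates 1 and 2. Adult globins have the highest median, and the neutrophil median (466 and 329) lies among those of the erythroid lists.

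Further lists described interferon, stress and sex-linked genes. Of 10 interferon response genes 6 were detected (9 by coding-scaled TPM), with a median of 34.9 ± 0.276 coding-scaled TPM. Rsad2, an antiviral enzyme gene, stood apart at 1901 ± 257, against 245 ± 70.4 for Isg15 and 3.08 ± 2.30 for Mx1. Of 12 immediate early and heat shock genes 3 were detected, namely Ddit3, Fos and Junb, while 11 reached 1 coding-scaled TPM, and the median was 10.3 ± 2.20. All 4 Y-linked genes were detected, with a median of 54.4 ± 4.77, while Xist had 11 and 0 counts, which goes with the male label. Of 10 long noncoding RNAs 5 were detected, with a list median TPM of 2.79 ± 1.74. Malat1 had a TPM of 1376 ± 411, Gas5 of 46.7 ± 1.49 and Neat1 of 18.5 ± 3.10.

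In all, 4829 genes were detected, of which 4360 were protein-coding. At 1 or more coding-scaled TPM in both libraries, a limit chosen after the data were seen, 9417 protein-coding genes passed. After the globins, the nuclear protein-coding genes of highest mean TPM were Gm10800, S100a8, Slc4a1, Tmcc2, Pabpc1, S100a9, Metap2, Gpx1, Cd24a, Alas2 and Hist2h2aa1. With the globins, these 15 genes held 45.0% and 40.8% of coding TPM in replicates 1 and 2. Gm10800 stood at 7900 and 20890 coding-scaled TPM in replicates 1 and 2, and whether its reads come from a messenger RNA was not tested.

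Small nuclear RNAs held the largest share of the deposited TPM. They took 43.4% of TPM in replicate 1 and 65.3% in replicate 2, against 11.3% and 6.89% for nuclear protein-coding genes. By counts the order was the opposite: 2.69% (95% Clopper-Pearson interval 2.68 to 2.69) and 12.02% (12.01 to 12.04) for small nuclear RNAs, against 57.7% and 52.4% for protein-coding genes. The intervals cover counting error of independent reads only, not the spread between the libraries. The 30 small nuclear RNAs with a mean TPM over 1000 had effective lengths of only 1.27 to 26.6 bases in replicate 1, so their TPM is high relative to their counts. The counts themselves were not few, at 1002784 and 2700611 for all small nuclear RNAs in replicates 1 and 2. The 7SL genes Rn7s1 and Rn7s2 share reads and had a TPM of 76157 ± 33339 and 76158 ± 33355. They were followed by the small nuclear RNA genes Gm24265 (65764 ± 71103), Gm23971 (46781 ± 15986) and Gm23849 (46727 ± 13825), of which the last pair share reads. Together with 7SK, the 7SL genes held 10.2% ± 0.264 of counts. Mitochondrial mRNA held 13.2% and 6.78% of counts, and mitochondrial ribosomal RNA 3.09% and 5.72%. Most mitochondrial mRNA counts came from 1 gene, mt-Co1, with 4402373 of 4930437 in replicate 1 and 1273783 of 1522281 in replicate 2. The gene mt-Co3 shares reads, with 79500 counts and a posterior standard deviation of 159953 in replicate 1. The share of mt-Co1 within the class is therefore an estimate. Long noncoding RNA held 6.94% ± 0.424 of counts and small nucleolar RNA 0.671% ± 0.449.

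**Figure D2:**
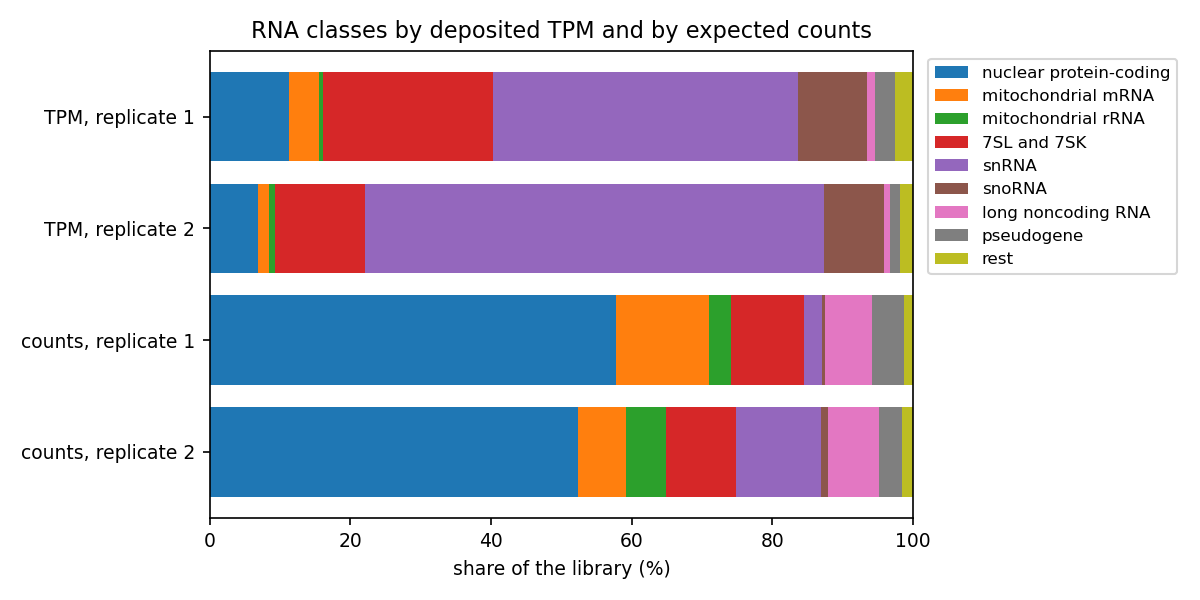
Share of each RNA class in each library (horizontal axis, percent), by deposited TPM and by expected counts. Small nuclear RNA fills 43.4% and 65.3% of TPM but 2.69% and 12.0% of counts.

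Single transcripts led several red cell genes. The leading transcript held over 50% in both libraries in 5 of the 9 genes detected, and the median leading share was 65.8% ± 10.4. A single transcript held 100% ± 0 of Gata1. The leading transcript held 94.4% ± 3.99 of Slc4a1, 90.9% ± 0.764 of Sptb and 65.8% ± 10.4 of Alas2. A transcript with a retained intron held 19.9% ± 7.57 of Alas2. No transcript held over 50% on average of Bcl2l1 (43.2% ± 4.81), Ank1 (35.9% ± 0.0919), Uros (32.9% ± 12.9) or Epb41 (24.7% ± 6.41). The Pklr gene was under the detection limit, and its transcripts are not described.

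The replicates ranked genes alike, and abundant protein-coding genes had similar levels in both. Across 12750 genes, which are not independent replicates, log2(TPM + 1) had a Pearson correlation of 0.948 and a Spearman correlation of 0.891. The biological coefficient of variation was 0.560 over 12757 genes, 0.453 over protein-coding genes and 0.317 for genes with a mean count of at least 100. Of 7658 protein-coding genes, 70.7% had a log2 ratio within 0.5 of the median. The variance between the libraries was 16.1 times the Poisson variance for protein-coding genes with mean counts of 20 to 50, 20.9 times for counts of 200 to 500 and 951 times above 20000.

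Small nuclear and nucleolar RNAs had higher counts in replicate 2. Of 38 small nuclear RNAs 37 were at least 2-fold higher there, with a median log2 ratio of 2.00. Of these 37, 22 share reads with similar sequences, so they are not separate measurements. Of 76 small nucleolar RNAs 60 were at least 2-fold higher in replicate 2, with a median of 2.69. Relative to nuclear protein-coding TPM, a measure chosen after the data were seen, small nuclear RNA stood at 385% and 947% in replicates 1 and 2. Small nucleolar RNA was also higher in replicate 2 by this measure (86.8% and 123%). Cajal body RNA was higher in replicate 2 by counts (0.0392% and 0.0736%, with 4 of 10 genes at least 2-fold higher). By the same measure relative to coding TPM it was lower (4.87% and 3.59%). As a share of all TPM, of which small nuclear RNA took a larger part in replicate 2, small nucleolar RNA held 9.77% and 8.50%. In all, 856 of 8203 genes were at least 2-fold apart, 398 higher in replicate 2 and 458 higher in replicate 1, against 0 in each of 100 simulations in which every read was an independent molecule. Among protein-coding genes 646 of 7658 were, 233 higher in replicate 2 and 413 higher in replicate 1. The split depends on the scaling: 46.5% of the 856 genes were higher in replicate 2 with TMM, 30.4% of 985 without scaling beyond library size and 5.20% of 2038 by the ratio of TPM. These settings move the median log2 ratio of all genes from -0.02 to -0.18 and -0.62. At a mean count of at least 1000, 84 genes of all RNA classes were higher in replicate 2 and 17 in replicate 1. Few of the 84 were protein-coding. Protein-coding genes higher in replicates 2 and 1 numbered 8 and 6 at counts of 1000 to 2000 and 3 and 1 at 2000 to 5000. They numbered 3 and 2 at counts of 5000 to 20000 and 1 and 0 above 20000.

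The 10 largest ratios toward replicate 2 comprised 5 small nucleolar RNAs, 3 small nuclear RNAs, a pseudogene and the histone gene Hist1h2ao. Snora36b had 0 and 431 counts, 267-fold higher in replicate 2 against a floor of 3 counts per library, and its interval began at a log2 ratio of 7.76. Gm24265 (chromosome 5, 115489459 to 115489599) had 11046 and 235057 counts, a log2 ratio of 5.30 (5.28 to 5.33), and Snora31 one of 5.18 (4.35 to 6.15). Hist1h2ao shares reads with other histone genes, and its log2 ratio of 8.72 is uncertain. Toward replicate 1, Ggnbp1 had 255.9 and 0 counts with shared reads (45.9-fold against the same floor, with an interval ending at a log2 ratio of -5.21). Tmem26 had a log2 ratio of -4.58 (-6.04 to -3.44) and Tmem175 one of -3.57 (-4.59 to -2.71). The remaining genes in that direction were 3 pseudogenes, a long noncoding RNA, the small nucleolar RNA gene Rnu3b4 and 2 genes without a symbol. Each ratio compares 2 libraries and has no replicate check.

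Most gene lists were not set apart from random lists by their ratios. Of 20 lists, 2 had a median log2 ratio outside the central 95% of random lists, where about 1 in 20 lies by chance. Neutrophil genes were lower in replicate 2, with a median of -0.25 at percentile 0.0900, and 10 of 14 members had a ratio below 0. Mpo had -0.87 (-0.90 to -0.83) and Ngp -0.80 (-0.82 to -0.77), while S100a9 had 0.69 (0.66 to 0.72). Adult globins had a median of -0.23 at percentile 1.49, which moved to percentile 7.02 with lists also matched on length. Of these 4 genes 3 were lower in replicate 2, while Hbb-bt was higher at 0.31 (0.30 to 0.32). Heme synthesis (0.10), red cell membrane (0.11), late maturation (-0.06) and cell cycle genes (0.02) lay within the central 95%. So did larger medians of lists with low counts, namely stem and progenitor genes at -0.46 (percentile 7.90, 8 of 9 members lower in replicate 2) and B cell genes at -1.20 on 3 members (percentile 3.57). With members at 0 counts in 1 library placed at their bound, these medians were -0.37 and -1.82.

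**Figure D3:**
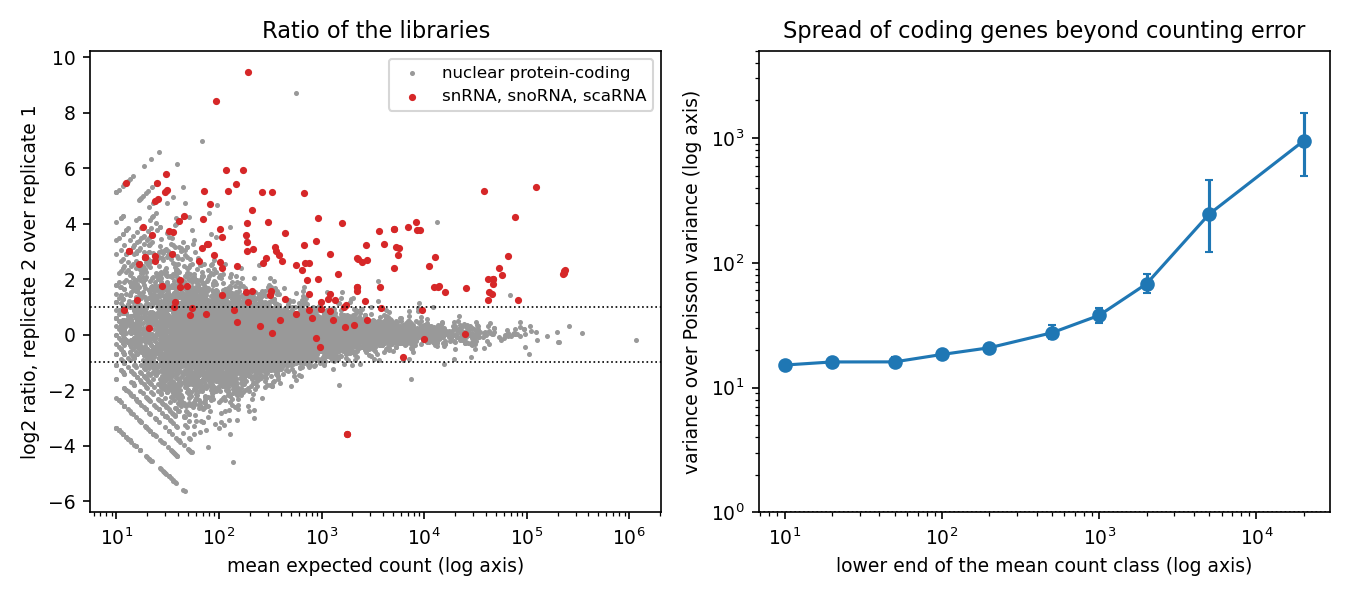
Left, log2 ratio of replicate 2 over replicate 1 against mean expected count (log axis) for protein-coding genes (grey) and small nuclear, nucleolar and Cajal body RNAs (red), with dotted lines at 2-fold and genes with 0 counts in a library left out. Right, mean variance between the libraries over the Poisson variance for protein-coding genes by class of mean count (both axes log, bars are 95% bootstrap intervals), which is 16.1 at counts of 20 to 50 and 951 above 20000.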

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

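The tests of fragment length and nuclear RNA below were chosen after the ratios were seen. The tRNA features, which no comparison used, held 8 counts in replicate 1 and 28 in replicate 2. In replicate 1 they fell on 1 of 26248 features and in replicate 2 on 4. The 97 spike-in features held 0 counts in both libraries.

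Small nuclear and nucleolar RNAs had higher counts in replicate 2, with small nuclear RNA at 4.47 times its share of counts in replicate 1. Relative to nuclear protein-coding TPM, small nuclear RNA was also higher there (385% and 947%). TPM takes effective length into account, so the estimated effective lengths did not remove this difference. Small nucleolar RNA was higher by the same measure (86.8% and 123%), but not as a share of all TPM (9.77% and 8.50%). Small nuclear RNA took a larger part of all TPM in replicate 2 (43.4% and 65.3%). More nuclear RNA in replicate 2 is argued against by Malat1, Neat1 and 7SK, whose median log2 ratio was 0.27 and whose highest value was 0.35. Shorter fragments in that library remain a candidate explanation. The median log2 ratio was 2.42 for 106 small noncoding RNAs under 200 bases and 1.24 for 15 of 200 to 300 bases. It was 0.11 for 8 of 300 bases and longer, which ranged from -0.70 to 1.71, with 2 still at least 2-fold higher. The middle values of these 8 are those of the 7SL genes Rn7s1 and Rn7s2, which share reads. The median of the longest class therefore rests on few separate RNAs. The labelled size range, 138 to 1000 for replicate 2 and 200 to 764 for replicate 1, was wider at both ends in replicate 2 and does not settle it by itself. The median difference between length and effective length, which grows with fragment length, was 190 bases in replicate 1 and 152 bases in replicate 2. The effective lengths point to shorter fragments in replicate 2, but how much of the small RNA difference they explain was not tested. A biological difference between the replicates in small RNA content was not tested.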

How the results depend on the processing

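The rescaling with globins kept, small RNA relative to coding TPM, the detection limit in coding-scaled TPM and the protein-coding restriction of detected genes and of ratios were chosen after seeing the data. No paired analysis was possible because the design has 1 group. Protein-coding genes held 9.07% of TPM but 55.1% of counts. Detected genes were 10261 at a TPM of 0.1, 978 at 10, 8742 by FPKM and 9417 in coding-scaled TPM, against 4829. The globin share was 5.59% of counts and 35.8% of coding TPM, against 3.31%. The erythroid median TPM of 38.0 became 666 when rescaled over coding genes without globins and 428 with them. The coefficient of variation of 0.560 became 0.317 at a minimum count of 100, 0.741 without a minimum and 0.453 for coding genes. For these settings Pearson's correlation was 0.964, 0.936 and 0.966 (0.919 with a pseudocount of 0.1), and Spearman's 0.922, 0.845 and 0.921. Genes at least 2-fold apart numbered 2038 by TPM ratio, 3347 at a minimum count of 10 and 101 at 1000, against 856. With lists matched on length, 1 list stood outside the central 95%, since adult globins moved inside. At a minimum count of 100, erythropoietin signalling moved outside, with a median of -0.33 at percentile 2.34. Other lists, classes and transcripts moved beyond their SD in 56 recomputations. Leaving out 1 of 2 libraries cannot move a mean beyond its SD and tests nothing here. The causes were not tested, except that a sum over fewer features raises a share by construction. Most genes at least 2-fold apart at a minimum count of 10 had mean counts under 100.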

Other observations

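The variance ratio, the lymphoid test and the interval of the maturation difference were chosen after the results were seen, as were the genes of the next paragraph.

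Mitochondrial transcripts differed between the replicates in both directions. Of 12 mitochondrial mRNAs with a mean count of at least 100, 2 were at least 2-fold higher in replicate 2 and 0 in replicate 1. The median log2 ratio of the 12 was -0.30. The ribosomal RNA genes mt-Rnr1 and mt-Rnr2 were higher in replicate 2, with log2 ratios of 1.90 (1.88 to 1.91) and 1.00. The mRNA mt-Co1 was lower there at -0.90 (-0.90 to -0.89), as were mt-Nd4 at -0.92 (-0.95 to -0.90) and mt-Nd1 at -0.79 (-0.80 to -0.77). Other mitochondrial mRNAs went the other way, with an interval of 1.43 to 1.58 for mt-Nd6 and a log2 ratio of 1.37 (1.33 to 1.41) for mt-Nd3, which shares reads. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462666), had 2678 and 23868 counts and a log2 ratio of 4.05 (3.99 to 4.11). Whether the Lars2 reads come from its messenger RNA was not tested, and neither was a link between Lars2 and the mitochondrial transcripts.

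Neutrophil granule genes were abundant in both erythroblast libraries. RNA of all marrow cell types alike is argued against by the 22 lymphoid genes, whose median was 0.666 coding-scaled TPM in replicate 1 and lower in replicate 2. RNA of neutrophil-lineage cells may be the source: of 25 further neutrophil genes, written down before their levels were looked up, 84.0% stood at 10 or more coding-scaled TPM in both libraries. The highest were Chil3 (675 ± 54.9) and Anxa1 (533 ± 125), and monocytes also express several of the 25, such as Tyrobp and Fcer1g. Ly6g (17.6 ± 11.2) and Cxcr2 (25.1 ± 1.28) were low. The limit of 10 is lenient, since Olfm4, at 9.56, stood at percentile 56.2 of the ranked protein-coding genes. The median of the 25 was 58.9 and 59.9 in replicates 1 and 2, against 466 and 329 for the fixed neutrophil list. The most abundant genes of that fixed list were S100a8 (8070 ± 918) and S100a9 (6041 ± 1769). Whether erythroblasts themselves transcribe these genes was not tested, and how the cells were isolated is not described in the sources used here.

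Among protein-coding genes, 646 were at least 2-fold apart. Counting error of independent reads does not account for these (at most 1 gene in any of 100 simulations). Over all protein-coding genes compared, transcript length explained 0.682% of the variance of the log2 ratio and GC content 0.356%. With each trend taken out in turn, 618 and 636 genes remained at least 2-fold apart, so neither accounts for most of the 646. The 646 genes were shorter than the rest, however. Their median length was 1687 bases where higher in replicate 2 and 2286 where higher in replicate 1, against 2570 for all. Reads that are copies of the same molecules may account for part: the variance over the Poisson variance grew by only 1.30 times from counts of 20 to 50 to counts of 200 to 500. Other causes of a spread that scales with the count were not separated from it, and the variance of 951 times Poisson above 20000 counts is left open. A different share of other marrow cells stays open, since the neutrophil median lay at -0.22 from that of all coding genes, the monocyte median at -0.16, the megakaryocyte median at -0.02 and the B cell median, on 3 genes, at -1.17. A different stage of maturation stays open too: cell cycle and late maturation medians differed by 0.0819, under the bound of 0.1 set beforehand to argue against it, but the later bootstrap interval of -0.13 to 0.28 is wider than that bound.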
